A study of Mus musculus with 32 samples.

How the data were processed

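Polyadenylated RNA was sequenced from E14 mouse embryonic stem cells, a male wild-type line, grown on gelatin in serum with LIF, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901. One arm (NrESC) also received 10 µM T0901317, a synthetic agonist of the liver X receptors (LXR), and the other arm (ESC) did not. Both arms were sampled at passages 0, 2, 4, 6, 8, 10, 12 and 14 with 2 libraries each, which gave 32 libraries in 16 groups. The labels mark every NrESC library as treated, passage 0 included, and do not say how long the cells had been treated at passage 0. They also do not say whether the 2 libraries of a group came from separate cultures, so all p-values below measure only the spread between these samples. No batch or date is labelled.

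The authors deposited expected counts per gene symbol, estimated by RSEM per the file headers and not normalized, and a second table in TPM, which the authors had corrected for gene length and scaled to an equal sum per library. Expected counts were mostly whole, with 0.837% of values fractional, and were rounded. Per the labels the processing used STAR, Cufflinks 2.2.1, HTSeq 0.12.4, DESeq2, edgeR and RSEM with the mm9 build, but the role of each tool, the annotation, read trimming and the strand setting were not stated. RSEM divides reads that match several genes among them, so values of near-identical gene copies depend on that division. Of the 24890 symbols, 24453 matched a GENCODE annotation of a later build, which was used only for gene names, GC content, transcript length and shared sequence words, and no coordinates are given. Dux was taken as the entry for Duxf3, and Tex13b as that for Tex13. The first of these pairs of names was not linked by either reference table.

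Library totals ran from 24989651 to 50463483 counts, TMM factors from 0.979 to 1.03, and the 10 highest genes held 4.89% to 5.76% of a library. Genes with too few counts were removed with edgeR's filterByExpr on the 16 groups, which left 15036 genes. A quasi-likelihood model with a mean per group (edgeR 4.0.16 in R 4.3.3, TMM scaling, 16 residual degrees of freedom) was fitted to all 32 libraries, and p-values were adjusted by the Benjamini-Hochberg method over all genes of each comparison, with a threshold of 0.05. The comparisons were NrESC against ESC in the mean of the 8 passages, at each passage, a test of whether that difference varied among passages, the slope over passage number in each arm in log2 per passage, and the difference of the slopes. Fold changes are on the log2 scale, NrESC over ESC, and levels are TMM-scaled CPM, counts relative to the library total. Standard errors (SE) come from this model. They reflect only the spread between the 2 libraries of a group, not the larger spread between passages. In the tests on simulated counts, 97% of genes changed by 1.2-fold and 100% of those changed by 2-fold were called in the mean of 8 passages, with 12 false calls among 209. At passage 14 alone 59% and 99% were called. These counts held only the spread between replicate libraries. In counts drawn with the spread between passages, 63% and 100% were called by the model with passage as the unit described below.

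Before the data were examined, 18 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists were LXR target genes, cholesterol synthesis, fatty acid synthesis, core and naive pluripotency, formative and primed pluripotency, 2-cell-like genes, trophectoderm, primitive endoderm, mesoderm and definitive endoderm, neuroectoderm, methylation-sensitive germline genes, imprinted genes, DNA methylation machinery, nuclear receptors, p53 targets, the integrated stress and unfolded protein response, glycolysis and hypoxia, and fibroblast markers as another cell type. They held 373 genes, of which 367 had an entry and 321 were tested. Lists were tested against all other genes with camera (limma 3.58.1, preset correlation of 0.01, adjusted over the 18 lists), with camera at an estimated correlation beside it, and with fry. Named genes were the 12 highest and 12 lowest fold changes in the mean of 8 passages among called genes with a mean log2 CPM of at least 1 and 1 sign at 8 of 8 passages. To these were added the 3 members of each list with the smallest p, the 5 highest and 5 lowest called slopes of each slope comparison, the 4 highest and 4 lowest called fold changes at passages 0 and 14, and 13 genes chosen in advance. Placeholder symbols were passed over, and genes named outside this rule are said to be so. Some genes that the rule names are not reported here.

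The 2 libraries of a group had a median SD of 0.0485 on the log2 scale, against 0.114 between ESC passages and 0.133 between NrESC passages. A model with passage as the unit was therefore added after the data were seen: libraries of each arm and passage were summed to 8 pairs, and the spread between passages was used (7 residual degrees of freedom). For the slopes, the same sums were fitted with a straight line in each arm and without the pairing by passage. Steps shared by both arms then count as spread, which can hide a difference of slopes. The biological coefficient of variation was 2.23% between replicate libraries and 9.85% with passage as the unit. The other alternatives were DESeq2 size factors, library totals alone, no filter, a filter of 1 CPM in 4 libraries, the DESeq2 test (version 1.42.0), limma on log2(TPM + 1), passages 2 to 14 only, the 4 libraries of a passage alone, a term for replicate number, a fold change bound, each library left out in turn, and, added after the data were seen, passage 8 left out. Hmgcs1, Zscan4e, Tcstv1, Tcstv3, B020031M17Rik and AF067061 are not analysed here. No standard error is given for genes with a group at 0, whose fitted values have none.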

Results

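The series compared mouse embryonic stem cells kept with the LXR agonist T0901317 (NrESC) with untreated cells of equal passage (ESC) over passages 0 to 14, and its title places this in the study of nuclear receptors and expanded pluripotency. Each of the 16 groups had 2 libraries. ESC libraries held 24989651 to 45818061 counts and NrESC libraries 25062538 to 50463483. The arms separated along the first principal component of log2 CPM, which held 35.9% of the variance, and passages 0 and 2 lay apart from later ones along the second, which held 17.8% (at -18.9 or lower, against -8.62 or higher). The NrESC libraries of passage 8 stood apart from all others, at 51.7 and 51.1 on the first component and 42.2 and 40.7 on the second. Transcripts of ribosomal protein genes took 6.71% ± 0.32 of the counts in ESC and 7.03% ± 0.339 in NrESC (SD over 8 passage means), and 7.68% in NrESC at passage 8. Histone transcripts, which mostly lack a poly(A) tail, took 0.00264% ± 0.00037 in ESC and 0.00397% ± 0.00137 in NrESC (SD over 8 passage means). They took 0.00663% and 0.00718% in the NrESC libraries of passage 4. Neither difference between the arms was tested.

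**Figure D1:**
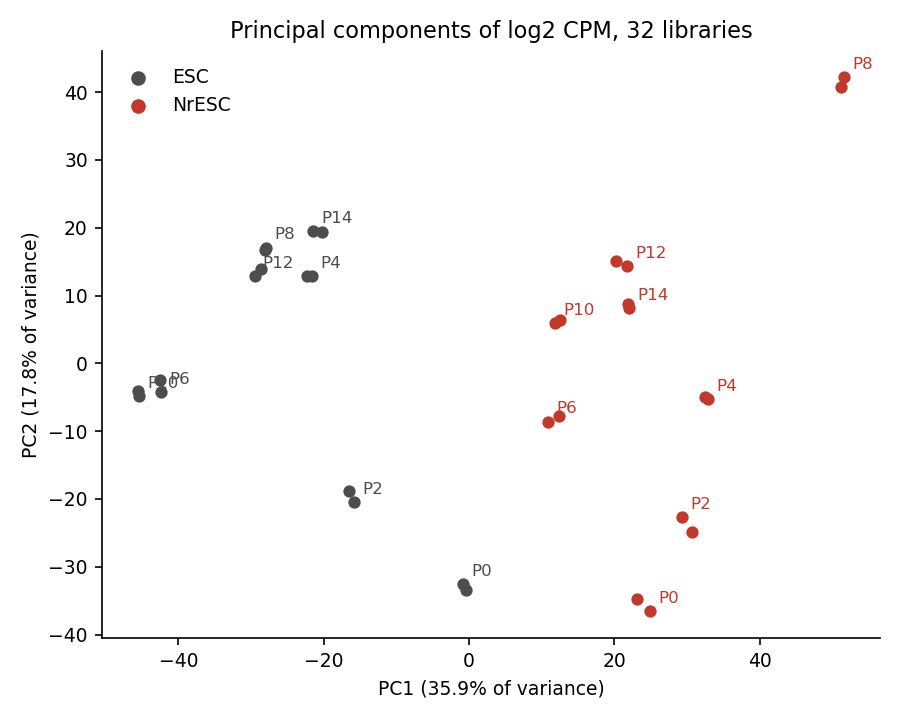
Principal components of log2 CPM for the 32 libraries, grey for ESC and red for NrESC, labelled by passage, with the share of variance on each axis. ESC and NrESC lie apart along the first component (35.9%), and the NrESC libraries of passage 8 lie beyond the rest at 51.7 and 51.1.

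The first question was what T0901317 changed in the mean of all passages. The transcripts of the sterol exporters Abcg1 and Abca1 rose most. Abcg1 went from 6.81 ± 1.62 CPM in ESC to 124 ± 34.3 in NrESC (SD over 8 passages), a log2 fold change of 4.18 (SE 0.021). Abca1 went from 49.1 ± 9.69 to 416 ± 33.7, a log2 fold change of 3.10 (SE 0.012). Each arm had 16 libraries, 2 at each of 8 passages, and these SEs measure the spread between the 2 libraries of a group only. Mylip, a ubiquitin ligase that targets the LDL receptor, rose by 2.27 (SE 0.028), and Srebf1, the transcription factor that drives fatty acid synthesis, by 1.73 (SE 0.013). All 4 were higher at 8 of 8 passages. Of the 20 LXR target genes tested, 19 rose and none fell, over all genes and adjusted over the list alone. Their median was 0.763 (camera adjusted p = 3.71e-132, adjusted p = 2.09e-09 with an estimated correlation). The receptors themselves were not called: Nr1h2 (LXR beta) had a log2 fold change of 0.04 (SE 0.017, adjusted p = 0.0599) and Nr1h3 (LXR alpha), at about 1 CPM in both arms, of 0.11 (SE 0.12, adjusted p = 0.387) in edgeR's quasi-likelihood test. Nr1h2 passed in several other settings, at most with a fold change of 0.05.

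Lipid synthesis rose with them. Of 17 fatty acid synthesis genes 15 rose and 1 fell, over all genes and adjusted over the list alone. Their median was 0.728 (camera adjusted p = 9.11e-88, adjusted p = 6.2e-08 with an estimated correlation). The stearoyl-CoA desaturase Scd1 went from 217 ± 57.4 to 994 ± 232 CPM (2.21, SE 0.0089), its paralog Scd2 from 1100 ± 235 to 3410 ± 281 CPM (1.66, SE 0.007), and Mid1ip1, a partner of acetyl-CoA carboxylase, rose by 2.24 (SE 0.02). Srebf1, Scd1, Scd2 and other members stand in both this list and that of LXR targets. Of 24 cholesterol synthesis genes 23 rose and none fell over all genes, and 23 rose and 1 fell adjusted over the list alone. Their median was smaller, at 0.474 (camera adjusted p = 9.02e-24, adjusted p = 1.73e-06 with an estimated correlation). Dhcr7, which makes cholesterol from its last precursor, rose by 0.81 (SE 0.011), the SREBP anchor Insig1 by 0.58 (SE 0.012) and the lanosterol synthase Lss by 0.57 (SE 0.011). At passage 8, where the NrESC libraries stood apart, the medians were 1.22 for LXR targets, 1.26 for fatty acid and 0.896 for cholesterol synthesis. At the other passages they ran from 0.607 to 0.865, 0.508 to 0.761 and 0.097 to 0.621.

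Genes of the 2-cell-like state, a rare state of stem cell cultures that transcribes genes of the 2-cell embryo, fell together. All 28 tested members fell, over all genes and adjusted over the list alone, each by more than 2-fold. Their median was -2.01 (camera adjusted p = 4.12e-16, adjusted p = 0.0017 with an estimated correlation). Zscan4c, a telomere-associated marker of that state, went from 27.8 ± 12.6 CPM in ESC to 6.31 ± 2.01 in NrESC (-2.00, SE 0.032), Zscan4d from 16.3 ± 8.11 to 3.48 ± 1.21 (-2.08, SE 0.046) and Gm5662 from 17.6 ± 8.23 to 3.72 ± 1.17 (-2.11, SE 0.042). Zscan4f (-2.10, SE 0.051), Zscan4a (-1.92, SE 0.037) and the deubiquitinase gene Usp17lb (-2.22, SE 0.091) fell as well. Dux, a transcription factor that switches the state on, was near the detection limit at 0.224 ± 0.103 against 0.0723 ± 0.0354 CPM (-1.62, SE 0.33, adjusted p = 1.24e-05 in edgeR's quasi-likelihood test). Many members are near-identical copies, so their separate values depend on how shared reads were divided.

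Pluripotency factors moved less and mostly down. Of 26 core and naive genes 21 fell and 5 rose, over all genes and adjusted over the list alone. Their median was -0.222 (camera adjusted p = 2.97e-06, adjusted p = 0.000241 with an estimated correlation). Nanog went from 1500 ± 181 to 1100 ± 158 CPM (-0.45, SE 0.0073), Sox2 from 383 ± 29.9 to 310 ± 55.7 (-0.32, SE 0.0094), Zfp42 fell by 0.32 (SE 0.008) and Dppa2, an activator of early embryonic genes, by 1.16 (SE 0.014). Pou5f1 rose from 1380 ± 121 to 1520 ± 81.3 CPM (0.15, SE 0.0089). Of 14 formative and primed genes 9 fell and 2 rose, over all genes and adjusted over the list alone (median -0.438, camera adjusted p = 0.00544, adjusted p = 0.0638 with an estimated correlation), among them Zic2 (-1.04, SE 0.022), Foxd3 (-1.0, SE 0.035) and Dnmt3b (-0.37, SE 0.012). The NrESC libraries of passage 8 had the lowest medians of both lists, -0.630 and -0.774, against -0.277 to -0.002 and -0.505 to -0.199 at the other passages.

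Lineage markers were not raised as groups. Of 21 trophectoderm genes 12 fell and 5 rose (median -0.241, camera adjusted p = 0.644): Cdx2, the trophectoderm regulator, went from 1.84 ± 0.846 to 0.767 ± 0.519 CPM (-1.36, SE 0.097) and Eomes fell by 0.44 (SE 0.02), whereas the keratin Krt8 rose from 35.8 ± 9.93 to 70.5 ± 20.2 CPM (0.98, SE 0.017). The imprinted Peg10, which is on this list too, fell by 0.28 (SE 0.009). Of 18 primitive endoderm genes 9 fell and 4 rose (median -0.142, camera adjusted p = 0.349), with Col4a1 at -0.54 (SE 0.018), Lama1 at -0.26 (SE 0.011) and Lamb1 at 0.34 (SE 0.017). The endoderm regulator Gata6, at about 1 CPM, was not called (-0.07, SE 0.1, adjusted p = 0.498 in edgeR's quasi-likelihood test), though it was without passage 8 (-0.28, adjusted p = 0.017). Of 12 mesoderm and definitive endoderm genes 8 fell and 2 rose (median -0.353, camera adjusted p = 0.000931, but 0.103 without a filter on low counts). The Nodal antagonist Lefty2 went from 203 ± 33.6 to 65.8 ± 26.5 CPM (-1.73, SE 0.013). Evx1, another member, was at 0.457 ± 0.379 CPM in ESC and 0.0434 ± 0.0435 in NrESC. Of 10 neuroectoderm genes 5 fell and 3 rose (median -0.120, camera adjusted p = 0.253), with Nes at -0.63 (SE 0.017), Tubb3 at -0.47 (SE 0.014) and Sox1 at 0.52 (SE 0.036). The counts of these 4 lists were equal when adjusted over the list alone.

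Germline genes that DNA methylation silences in other cells fell in 11 of 20 cases and rose in 6 (median -0.200, camera adjusted p = 0.0489, adjusted p = 0.0801 with an estimated correlation). The meiotic genes Hormad1 (-1.09, SE 0.033), Tex15 (-0.81, SE 0.02) and Fkbp6 (-0.81, SE 0.022) fell. Of 28 imprinted genes 12 rose and 12 fell (median -0.003, camera adjusted p = 0.480). H19, a maternally expressed noncoding RNA, went from 24.6 ± 16.5 to 4.03 ± 1.44 CPM (-2.30, SE 0.035), Impact fell by 0.67 (SE 0.012) and Plagl1 by 0.45 (SE 0.01). Of 11 genes of the DNA methylation machinery 8 fell and 1 rose (median -0.089, camera adjusted p = 0.00342), with Dnmt3b at -0.37, the demethylase Tet2 at -0.34 (SE 0.0093) and the histone methyltransferase Setdb1 at -0.29 (SE 0.0093). That list had a median of -0.475 in the passage 8 libraries against -0.151 to -0.024 elsewhere, and it was not called without passage 8 (adjusted p = 0.0522) or with passage as the unit (adjusted p = 0.151). The counts of these 3 lists were equal when adjusted over the list alone.

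Among the remaining lists the integrated stress and unfolded protein response rose: 14 of 20 genes were higher and 4 lower. Their median was 0.503 (camera adjusted p = 3.88e-20, adjusted p = 3.05e-05 with an estimated correlation). The members with the smallest p were the serine synthesis genes Phgdh (129 ± 27.2 to 266 ± 36.8 CPM, 1.05, SE 0.012) and Psat1 (0.75, SE 0.0082) and the stress-induced pseudokinase Trib3 (1.17, SE 0.018). A rise of 2-fold or more was seen in 6 members, so some not named here rose more than Psat1. The median of the list was 0.817 at passage 8 against 0.315 to 0.562 elsewhere. Of 27 nuclear receptors 15 fell and 4 rose (median -0.082, camera adjusted p = 0.640), with the retinoic acid receptors Rara at 0.61 (SE 0.015) and Rarg at -0.55 (SE 0.015), and Nr6a1 at -0.29 (SE 0.014). Of 20 p53 targets 11 fell and 8 rose, and the median of -0.112 and the mean of 0.011 differed in sign (camera direction down, adjusted p = 0.947). The cell cycle inhibitor Cdkn1a rose by 0.43 (SE 0.0094), Ddit4 by 0.74 (SE 0.017), and the apoptosis gene Pmaip1 fell by 0.88 (SE 0.022). Of 19 glycolysis and hypoxia genes 10 fell and 6 rose (median -0.039, camera adjusted p = 0.644), with the hexokinase Hk1 at 0.55 (SE 0.0091), Bnip3 at -0.72 (SE 0.016) and Ldha at -0.28 (SE 0.0069). Of 7 fibroblast markers 3 rose and 2 fell, with a median of 0.131, a mean of -0.017 and a camera direction of down (adjusted p = 0.440). Vim fell by 0.49 (SE 0.0099), Fbn1 by 0.40 (SE 0.036), and Pdgfrb rose by 0.31 (SE 0.024). The counts of these 5 lists were equal when adjusted over the list alone. Of the 18 lists 10 were called by camera, 4 up and 6 down, and 8 of these also with an estimated correlation, the exceptions being the formative and the germline list. In that setting the adjusted p of the 8 ran from 2.09e-09 to 0.0119.

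Outside the lists, genes with raised transcripts included the transcription factor Mef2b (1.86, SE 0.062), the insulin-responsive glucose transporter Slc2a4 (1.81, SE 0.076), Ubap1l (1.75, SE 0.04), the interferon regulatory factor Irf8 (1.70, SE 0.054) and the amino acid oxidase Il4i1 (1.68, SE 0.13). The lysine-degrading enzyme Aass had the lowest fold change of the named genes that had no group at 0 (-3.17, SE 0.082), followed by the PRAME family members Pramel6 (-2.93, SE 0.041) and Pramel7 (-2.83, SE 0.054). The zinc finger gene Zfp951 (-2.29, SE 0.043), Smtnl1 (-2.23, SE 0.048) and Mobp (-2.00, SE 0.083) also fell. In all, 5880 of 15036 genes rose and 5988 fell in edgeR's quasi-likelihood test, most of them slightly: 257 rose and 505 fell by 2-fold or more. Both libraries of a group were so alike that small differences passed. With passage as the unit, 4258 rose and 4083 fell, and 8332 of those were called in both models with the same direction. The fold change had 1 sign at 8 of 8 passages for 5719 of the called genes.

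**Figure D2:**
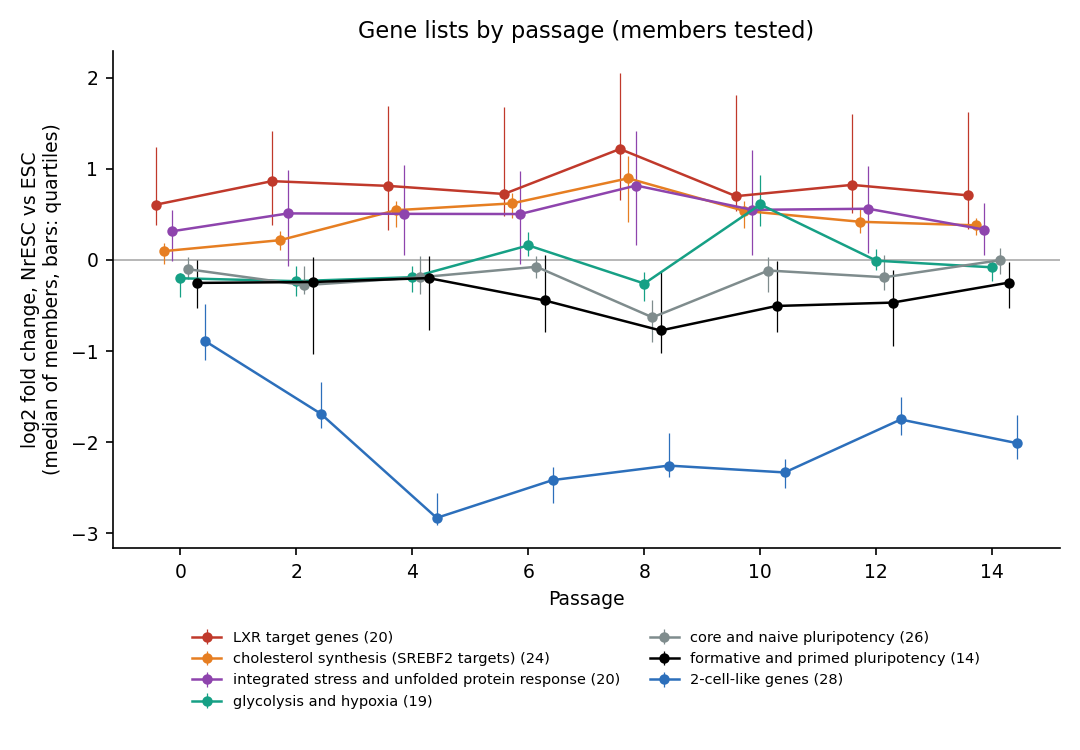
Median log2 fold change of NrESC over ESC (y axis) of 7 gene lists at each passage (x axis), with bars from the lower to the upper quartile of the members and the number tested in the key. LXR targets stay between 0.607 and 1.22, 2-cell-like genes go from -0.887 at passage 0 to -2.83 at passage 4, -1.75 at passage 12 and -2.01 at passage 14, and glycolysis genes peak at 0.609 at passage 10.

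At passage 0 the LXR targets were already raised. Abcg1 was higher by 4.21 (SE 0.065, n = 2 libraries per arm), Abca1 by 3.30 (SE 0.035), Mylip by 2.32 (SE 0.074) and the cytolinker gene Eppk1 by 1.76 (SE 0.096). The collagen cross-linking enzyme Loxl2 was lower (-1.82, SE 0.11), as were the kinesin Kif19a (-1.79, SE 0.25), the amine oxidase Aoc3 (-1.71, SE 0.28) and the protease inhibitor A2m (-1.64, SE 0.055). Of 20 LXR targets 16 rose, whereas of 24 cholesterol synthesis genes 12 rose and 4 fell (median 0.097, camera adjusted p = 0.0398), and 10 of 28 2-cell-like genes fell (median -0.887). In total 2645 genes rose and 2230 fell in edgeR's quasi-likelihood test, 106 and 130 of them by 2-fold or more.

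At passage 14 Abcg1 (4.09, SE 0.063), Abca1 (3.33, SE 0.035) and Mid1ip1 (2.22, SE 0.058) were higher, and the antiproliferative gene Btg3, at 0.481 CPM in ESC and 3.26 in NrESC, was higher by 2.79 (SE 0.59, adjusted p = 0.000176 in edgeR's quasi-likelihood test). The lowest called fold changes among genes with a mean log2 CPM of at least 1 were those of Aass (-4.74, SE 0.22, against -0.08, SE 0.13, at passage 0), Zfp951 (-3.61, SE 0.14, against -0.24, SE 0.086), the MHC class II gene H2-Eb1 (-3.30, SE 0.21, against 0.11, SE 0.2) and Pramel7 (-3.29, SE 0.14, against -1.05, SE 0.16). Of 28 2-cell-like genes 25 fell (median -2.01), after medians of -1.69 at passage 2, -2.83 at passage 4, -2.42 at passage 6, -2.26 at passage 8, -2.33 at passage 10 and -1.75 at passage 12. Of 21 trophectoderm genes 14 fell and 3 rose (camera adjusted p = 0.00556), and of 26 pluripotency genes 8 fell and 8 rose (median -0.002, camera adjusted p = 0.478). In total 2968 genes rose and 3202 fell, 119 and 542 of them by 2-fold or more.

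The passages between them had 3720 genes up and 3573 down at passage 2, 4120 and 4038 at passage 4, 3547 and 3775 at passage 6, 4056 and 4289 at passage 10, and 3480 and 3609 at passage 12. Passage 8 had 5291 up and 5199 down, and 1106 and 996 of these changed by 2-fold or more. The SD of the fold changes over genes was 0.529 there and 0.232 to 0.354 at the other passages. Abcg1 reached 205 ± 4.4 CPM in NrESC at passage 8 (SD, n = 2), and Nanog dropped to 853 ± 14 CPM, the lowest group mean of the series. Some 968 genes were raised and 751 lowered at each of the 8 passages.

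**Figure D3:**
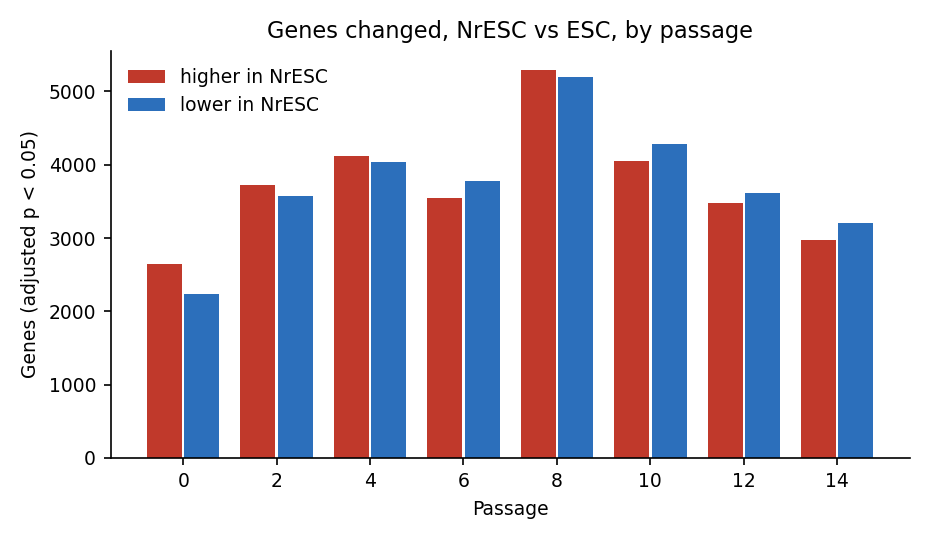
Number of genes called higher and lower in NrESC than in ESC (y axis) at each passage (x axis) by edgeR's quasi-likelihood test at an adjusted p of 0.05, red for higher and blue for lower. Passage 8 has the most, 5291 up and 5199 down, and passage 0 the fewest, 2645 and 2230.

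The next question was whether the difference between the arms changed over the passages. It varied among passages for 10436 genes (7984 without passage 8). The slope was higher in NrESC than in ESC for Btg3 (0.12 log2 per passage, SE 0.042), the calcium buffer Calb2 (0.12, SE 0.0066), Loxl2 (0.11, SE 0.0071), the kallikrein Klk1 (0.10, SE 0.014) and Slfn9 (0.10, SE 0.0066). It was lower for Aass (-0.30, SE 0.02), Zfp951 (-0.26, SE 0.0094), H2-Eb1 (-0.25, SE 0.021), the Y-linked ubiquitin-activating enzyme Uba1y (-0.21, SE 0.007) and the tryptophan-degrading enzyme Ido2 (-0.20, SE 0.013). Btg3 went from 2.10 ± 1.2 CPM at passage 0 to 0.481 ± 0.21 at passage 14 in ESC and from 3.34 ± 0.39 to 3.26 ± 0.00034 in NrESC. Zfp951 went from 16.3 ± 1 CPM at passage 0 to 1.26 ± 0.018 at passage 14 in NrESC and from 19.3 ± 0.1 to 15.3 ± 1.5 in ESC, and Uba1y from 23.4 ± 0.31 to 3.12 ± 0.059 against 20.1 ± 0.43 to 16.8 ± 0.12 (SD, n = 2). H2-Eb1 went from 2.21 ± 0.14 to 7.69 ± 0.3 CPM in ESC and from 2.44 ± 0.42 to 0.777 ± 0.036 in NrESC. Several of these were not steady changes. In NrESC, Aass dropped from 5.91 CPM at passage 0 to 0.512 at passage 2 and stood at 0.295 to 0.454 from passage 4 on. H2-Eb1 stood at 0.304 to 0.777 CPM in NrESC from passage 2 on. Btg3 ran from 0.418 to 2.34 CPM in ESC at passages 4 to 14.

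Among the lists, cholesterol synthesis had a higher slope in NrESC than in ESC (median 0.0208 log2 per passage, camera adjusted p = 1.52e-23), as did glycolysis (0.0230, adjusted p = 3.87e-61). Lower slopes were those of trophectoderm (-0.0304, adjusted p = 3.48e-05), germline (-0.0170, adjusted p = 0.00343) and imprinted genes (-0.0132, adjusted p = 2.93e-05). With an estimated correlation these 5 gave adjusted p of 4.14e-08, 4.14e-08, 0.00287, 0.0099 and 0.000665. These slopes were not steady changes: the cholesterol median went from 0.097 at passage 0 to 0.896 at passage 8 and 0.380 at passage 14, and the glycolysis median was -0.201 at passage 0, 0.160 at passage 6, -0.259 at passage 8, 0.609 at passage 10 and -0.081 at passage 14. With passage as the unit these 5 gave adjusted p of 1.31e-06, 4.77e-06, 0.00015, 0.000958 and 0.00215. Over all genes 1693 slope differences were above 0 and 2130 below in edgeR's quasi-likelihood test, but with passage as the unit only 2 remained past the threshold. These were Xlr3b (-0.10, adjusted p = 0.0195) and Xlr4a (-0.11, adjusted p = 0.0242), X-linked members of a lymphocyte-regulated family that the naming rule does not cover. The 10 genes named above thus rest on the spread between replicate libraries alone. That model does not pair the passages for slopes, so shifts shared by both arms may have lowered its count, which was not tested. Btg3 also failed in the DESeq2 test (adjusted p = 0.14) and in limma on TPM (adjusted p = 0.0711).

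**Figure D4:**
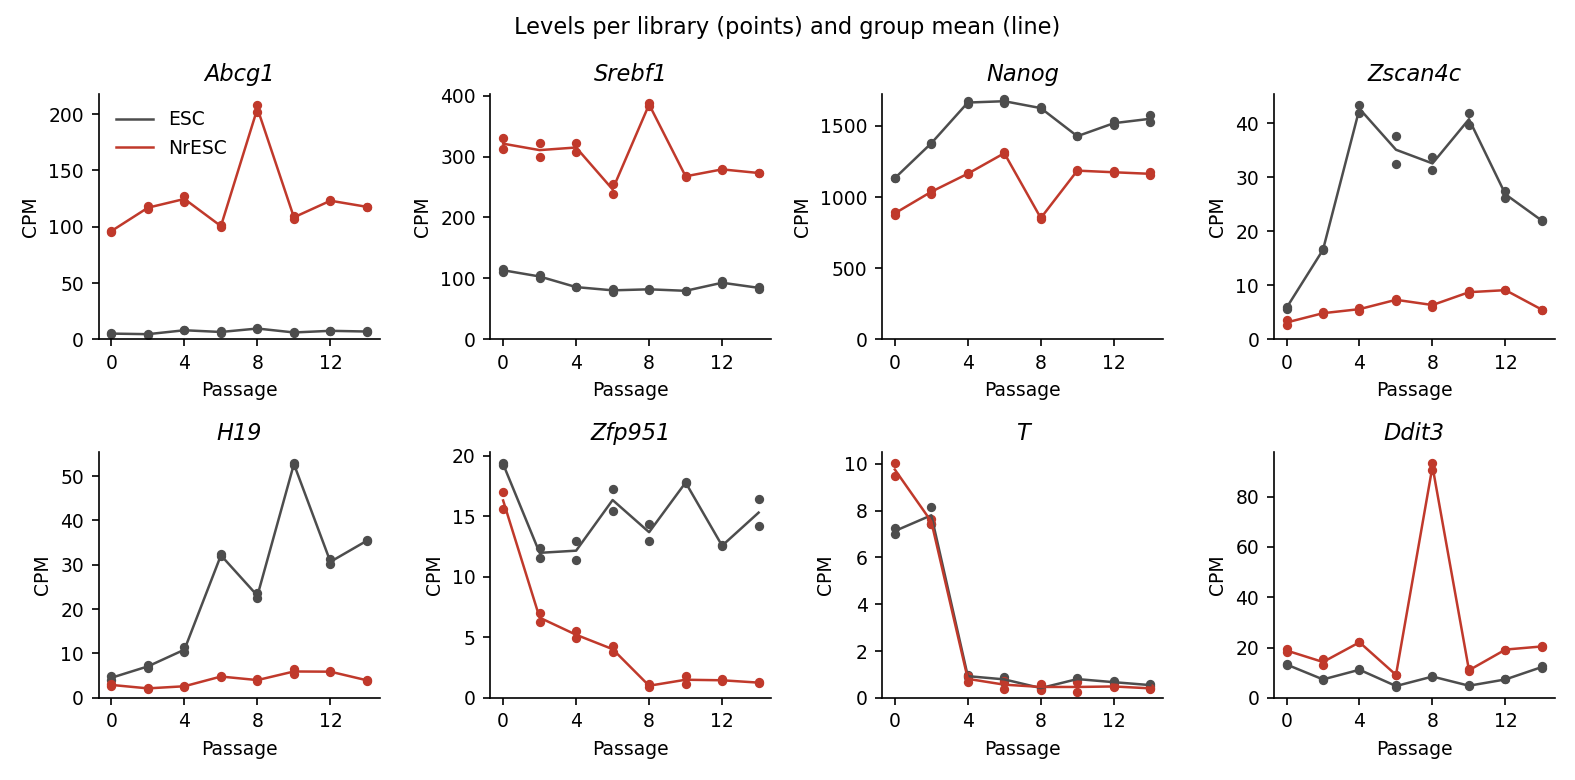
CPM (y axes, from 0) of 8 genes over passage (x axes), with a point per library and a line through the group means, grey for ESC and red for NrESC. Ddit3 was added after its values were seen; it reaches 92.0 CPM in NrESC at passage 8, while T falls below 1 CPM in both arms after passage 2.

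The slopes within each arm describe which transcripts went up or down over the passages with and without the agonist. A slope can come from a single step: T was at 7.13 to 7.80 CPM in ESC at passages 0 and 2 and at 0.417 to 0.927 from passage 4 on, and Sp5 at 26.5 to 30.3 and then 4.12 to 6.61. In ESC, H19 rose from 4.53 ± 0.6 CPM at passage 0 to 35.4 ± 0.15 at passage 14 (0.22 log2 per passage, SE 0.0045), and its neighbour Igf2 from 0.987 ± 0.04 to 7.88 ± 0.2 (0.18, SE 0.01). H2-Eb1 (0.21, SE 0.01), the cadherin Fat2 (0.20, SE 0.014) and the collagen receptor Ddr2 (0.18, SE 0.0051) rose as well. T (brachyury), a mesoderm regulator and Wnt target, fell from 7.13 ± 0.18 to 0.544 ± 0.065 CPM (-0.27, SE 0.012), and the serotonin receptor Htr5a (-0.25, SE 0.0072), the Wnt target Sp5 (-0.19, SE 0.006) and the DNA sensor Aim2 (-0.16, SE 0.0036) fell with it. In total 4095 genes rose and 4238 fell in edgeR's quasi-likelihood test, 4786 and 3451 when scaled by library totals alone, and 33 and 39 with passage as the unit. H19, Igf2, T, Htr5a and Aim2 were among the latter, whereas H2-Eb1, Fat2, Ddr2 and Sp5 were not (adjusted p of 0.0924 to 0.225).

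In NrESC, Fat2 (0.30 log2 per passage, SE 0.017), the carbonic anhydrase Car12 (0.19, SE 0.015), the calcium channel Cacna1h (0.18, SE 0.0099) and Rassf4 (0.17, SE 0.0082) rose. Amd1 had a higher fitted slope, but it had groups at 0 and no slope is given. T fell from 9.76 ± 0.37 to 0.406 ± 0.024 CPM (-0.32, SE 0.013), Sp5 (-0.27, SE 0.0061) and Htr5a (-0.27, SE 0.0057) fell as in ESC, and Zfp951 (-0.26, SE 0.0077) and Ido2 (-0.24, SE 0.01) fell too. In total 4296 genes rose and 4709 fell, 4932 and 4045 when scaled by library totals alone, and 112 and 249 with passage as the unit, which kept Car12, T, Sp5, Htr5a, Zfp951 and Ido2. Of 6252 genes with a called slope in both arms 5854 had 1 direction and 398 opposite directions. H19 had a smaller slope in NrESC (0.08, SE 0.0068), and the difference from ESC of -0.14 (SE 0.0086, adjusted p = 3.79e-17 in edgeR's quasi-likelihood test) was not called with passage as the unit.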

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

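The tests of depth, of short-lived transcripts, of shared reads, of the ESC rise and of hypoxia targets, passage as the unit, and leaving out passages 8 or 10, were chosen only after the results they bear on had been seen. The 20 values tested for a passage that stands apart share libraries, and some lists share members, so they are not independent. Passage 8 stood apart from the other 7 passages in 6 of these 20, where chance gives about 1 in 20 for a single value. These were the SD of the fold changes (0.529) and the median fold changes of LXR targets (1.22), fatty acid synthesis (1.26), pluripotency genes (-0.63), neuroectoderm genes (0.181) and the DNA methylation machinery (-0.475).

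The distance of NrESC at passage 8 was weighed against 3 technical causes. A bias in GC content or transcript length is argued against, since the SD was 0.529 before and 0.52 after that trend was taken out, with 0.354 the highest elsewhere. Depth is argued against too: the totals of 30460590 to 37587923 counts lay inside the range of the other libraries, and genes above a log2 CPM of 6 kept an SD of 0.421, against at most 0.274 at other passages. A loss of short-lived transcripts at harvest may have contributed and stays open, because 243 zinc finger genes had a median of -0.292 against passages 6 and 10, just short of the bound set for it, and at least -0.056 in the other steps of that kind. No biological explanation was tested, and none of these tests says what set the passage 8 cultures apart.

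The lower 2-cell-like genes in NrESC were weighed against reads shared between copies. The 4 members with under 5% of their 50-base words in other genes had a median of -1.82 (from -1.98 to -1.73), which argues against sharing as the whole cause. The narrow range depends on that bound: Obox6, just past it at 5.02%, had the smallest drop of the list (-1.244). A candidate explanation is that these genes rose in ESC after passage 0 and less so in NrESC: from passage 0 to passages 4 to 14 the median rose by 2.444 in ESC, with 28 of 28 members up, and by 1.147 in NrESC, with 18 up. The median difference between these changes was -1.343, with 15 of 28 members lower (camera adjusted p = 3.97e-07, adjusted p = 0.0029 with an estimated correlation), but it restates the gap already seen, which was widest at passage 4, and the planned test of the slope difference was not passed with an estimated correlation (adjusted p = 0.111). It is a hypothesis on which arm moved, not why, and it leaves the lower level at passage 0, a median of -0.887, unaccounted for.

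The glycolysis list was lower in NrESC at passages 0, 2, 4, 8 and 14 and higher at passages 6 and 10. GC content and length are argued against, since after that trend was taken out the median was 0.582 at passage 10 and -0.275 at passage 0. Oxygen supply or cell density that differed between dishes might account for it, and 15 hypoxia targets outside the list were compared with it over the 8 passages, the only relation computed. Spearman's rho was 0.548 (exact permutation p = 0.171, two-sided) and Pearson's r 0.947 (exact permutation p = 0.00533), but r was 0.325 without passages 6 and 10. The relation rests on those passages: the outside targets were below 0 at 7 of 8 passages, and at passage 6 they and the list had their second highest medians, -0.157 (1 up, 8 down) and 0.160, while at passage 10 they had 0.355 (11 up, 3 down), so the explanation stays open.

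The difference between the arms varied among passages for 10436 genes, and the slopes differed for 3823. Among named genes the slope differences were 0.1197 for Btg3, 0.1162 for Calb2, 0.1095 for Loxl2, 0.0999 for Klk1, 0.0989 for Slfn9, -0.2988 for Aass, -0.2592 for Zfp951, -0.2506 for H2-Eb1, -0.208 for Uba1y and -0.1988 for Ido2, and none of the 10 passed with passage as the unit. Slopes of 11 lists differed by camera. Those higher in NrESC were LXR targets (adjusted p = 0.0011), cholesterol synthesis (1.52e-23), fatty acid synthesis (3.1e-09), the stress response (0.000119) and glycolysis (3.87e-61). Those lower were 2-cell-like (0.0263), trophectoderm (3.48e-05), germline (0.00343), imprinted (2.93e-05), DNA methylation (0.0453) and p53 target genes (0.00289). With an estimated correlation, glycolysis and cholesterol synthesis each had an adjusted p = 4.14e-08. In that setting 2-cell-like genes had an adjusted p = 0.111 and the DNA methylation machinery an adjusted p = 0.0618. With passage as the unit the 2-cell-like genes and the DNA methylation machinery, with adjusted p of 0.0792 and 0.365, and LXR targets, with 0.547, were not called. Without passage 8 the core and naive pluripotency list was called as higher (0.0581 with it, 0.000855 without) and the DNA methylation machinery was not (0.367). Without passage 10 the 2-cell-like genes (0.0519) and the DNA methylation machinery (0.0849) were not called.

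Regrouping the samples in 60 ways per comparison, the real one included, tested whether chance could give such counts. For the mean of 8 passages a random labelling of the arms can be excluded only if passages are taken as independent. No other regrouping of libraries within passages gave more than 5277 genes against 11868. Such regroupings part the 2 alike libraries of a group, which widens the spread within groups and lowers the count. Exchanging the arms at whole passages gave at most 11230, a narrow margin, or 3042 against 8341 with passage as the unit. A lasting difference between the cultures of the arms, apart from the agonist, would give the same counts and is not excluded. For the slope in ESC a random order can be excluded, by a narrow margin with the replicate spread (8333 against at most 8262 in another order of passages) and with passage as the unit (72 against 23). These reorderings treat passages as exchangeable, and successive samples of a culture are not, so an undirected drift is not excluded for any of the slope counts. For the slope in NrESC a random order cannot be excluded with the replicate spread, where 6 of 60 orders gave as many (9005 against up to 9864). With passage as the unit 2 of 60 did, the real one included, which passed the bound set in advance. Another order still gave 1063 genes against 361, so a random order is not firmly excluded there. For the slope difference a random order cannot be excluded with the replicate spread, where 28 did (3823 against up to 6886), and with passage as the unit no other order gave more than 1 gene, against 2.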

How the results depend on the processing

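The settings passage as the unit and passage 8 left out were chosen after seeing the data, as was passage 10 left out for the list slopes, and the rest in advance. No named gene and no called list reversed its direction, while the more frequent direction of several counts did, as given below. The count for the mean of 8 passages (11868) stayed between 8341 (passage as the unit) and 12048 (no filter), apart from 762 genes (257 up, 505 down) with a fold change bound of 2-fold, which keeps fewer by construction, and 11740 to 11871 with each library left out in turn. Leaving out a library left an arm with 1 sample at that passage, assumed to vary like the other groups; counts at single passages then ran from 3378 (passage 0) to 9707 (passage 8), none moving by over 1.5 times. With passage as the unit the slope difference was called for 2 genes (against 3823), the slope in ESC for 72 (against 8333) and that in NrESC for 361 (against 9005). That setting replaces the spread between replicate libraries by the larger spread between passages. For the slopes it also leaves the passages unpaired and counts departures from a straight line as spread. Of 18 lists 10 were called, 8 to 10 in the other settings of camera, and 17 (4 up, 13 down) with fry, which asks whether a list's genes move and not whether they move more than other genes. The germline list was not called with DESeq2 size factors (adjusted p = 0.0541), without a filter (0.121), with an estimated correlation (0.0801), or without ESC passage 0 replicate 1 (0.0505), ESC passage 2 replicate 1 (0.0534), ESC passage 4 replicate 2 (0.0515) or NrESC passage 4 replicate 2 (0.0507). The mesoderm list was not called without a filter (0.103).

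The more frequent direction of the counts turned with the scaling, and in some counts with the filter, the test or the libraries fitted. Without a filter it turned for passages 6 (3612 up, 3582 down), 12 (3538 and 3453) and 14 (3054 and 3013). With the filter of 1 CPM in 4 libraries it turned for passages 4 (3905 and 3940), 8 (4840 and 4991) and 10 (4034 and 3970), and for the slope in ESC (3944 and 3893). With library totals alone it turned for the mean of 8 passages (6130 up, 5718 down, against 5880 and 5988), for passages 4 (3933 and 4194), 6 (3673 and 3648), 10 (4610 and 3697) and 12 (3738 and 3399), and for the slopes in ESC (4786 and 3451) and NrESC (4932 and 4045). With DESeq2 size factors it turned for passages 0 (2423 and 2437), 2 (3543 and 3773), 4 (3996 and 4149) and 8 (5051 and 5441). The DESeq2 test turned it for the same passages, 0 (2012 and 2094), 2 (3095 and 3335), 4 (3566 and 3722) and 8 (4634 and 5118). With the 4 libraries of a passage alone it turned for passages 0 (2301 and 2320) and 10 (4386 and 4266). With passage as the unit it turned for the mean of 8 passages (4258 and 4083), and in limma on log2(TPM + 1) for passage 8 (4337 and 5240). In limma on log2(TPM + 1), 2895 genes were higher and 4940 lower at passage 4, a share of 36.9% against 50.5%, and the upward share of slopes was 69.1% in ESC and 65.3% in NrESC, against 49.1% and 47.7%; the cause was not tested. No scaling moved the median of all genes by over 0.1. Of 4440 values of named genes under other settings 4390 kept their side of the threshold, 35 lost their call and 15 gained it. Most of these values came from leaving out 1 library, which changes little. With passage as the unit 87 kept their side and 19 lost their call, among them the 10 slope differences named above. Replicate numbers did not pair the samples at most passages: the correlation of their differences between arms ran from -0.213 to 0.519 and exceeded 0.1 in 2 of 8. At those passages, 6 (0.492) and 12 (0.519), libraries of equal number deviated together, and the reason was not tested. A replicate term within passages gave 11737 genes and 10 lists. No setting varied the depth, so what it limits was not measured. In simulated counts at the depth of these libraries, 97% of changes of 1.2-fold were called in the mean of 8 passages and 59% at passage 14 alone. Those counts held only the spread between replicate libraries, and 63% were called with passage as the unit in counts with the spread between passages.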

Other observations

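The tests of Wnt targets and the genes named here were chosen only after values had been seen. The NrESC libraries of passage 8 differed from the other 15 groups in several genes that the naming rule does not cover. Of these, Ddit3 belongs to the stress response list and Gata2 to the trophectoderm list, so they are not independent of those lists. Ddit3, a stress-induced transcription factor, stood at 92.0 CPM against 4.69 to 22.1 in the others, Txnip, a thioredoxin inhibitor, at 591 against 160 to 264, and Gata2, a haematopoietic and trophoblast regulator, at 35.6 against 3.79 to 15.6. Id3, a target of BMP signalling, stood at 0.785 CPM against 5.14 to 41.3, and Myc at 2.02 against 7.02 to 37.6. The immediate early gene Egr1 stood at 64.1 ± 2.6 CPM in ESC and 10.6 ± 0.72 in NrESC at passage 2 (SD, n = 2), and at 0.267 to 1.27 in the other 14 groups.

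All 9 tested genes of the X-linked Xlr3, Xlr4 and Xlr5 families had a called negative slope difference between NrESC and ESC, and 2 of them, Xlr3b and Xlr4a, also with passage as the unit. Xlr3c went from 26 CPM at passage 0 to 2.82 at passage 14 in NrESC and from 26.8 to 19.3 in ESC. The copies are near-identical, so values of single members are uncertain. The Y-linked Ddx3y stood at 67.9 ± 0.26 CPM in NrESC and 62.3 ± 1.6 in ESC at passage 14, while Uba1y, on the same chromosome, stood at 3.12 and 16.8.

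Between passages 2 and 4, targets of beta-catenin signalling dropped in both arms: T from 7.80 to 0.927 CPM in ESC and from 7.53 to 0.811 in NrESC, Sp5 from 30.3 to 5.41 and from 29.3 to 5.50, Axin2 from 90.5 to 46.3 and from 86.4 to 43.9, and Cdx1 from 145 to 78.5 and from 170 to 94.3. As a hypothesis, the whole beta-catenin programme may have dropped, and 14 targets not used to notice the step were tested. Their median step was -0.387 in ESC, with 7 down and none up, and -0.291 in NrESC, with 6 down and none up (camera adjusted p = 1.05e-05 in both, adjusted p = 0.000441 with an estimated correlation). The NrESC median fell just short of the bound of -0.3 set for it, so the hypothesis stays open. A batch that parts passages 0 and 2 from the rest stays open too: the labels give none, and the SD of this step over all genes was the highest of the 7 steps in ESC (0.259) and the median of the 7 in NrESC (0.188).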
